A study of Homo sapiens with 6 samples.

How the data were processed

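Total RNA of KhES-1 cells in AKIT or E8 medium was purified with a silica column kit and made into Illumina libraries, per the labels' protocols. The deposited table gives RPKM, read counts scaled by gene length and library depth, for 23346 gene rows by symbol. The authors normalized these values before deposit, and the submitters' processing notes name the builds hg19 and GRCh37. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here. Each column was matched to its sample by the sample title. The series holds 6 samples, and RPKM columns of 5 were used: AKIT replicates 1 to 3 and E8 replicates 1 and 2. E8 replicate 3 was not used here, so the planned comparison of 3 with 3 libraries was run as 3 with 2. No coordinates are given, because the annotation used here is of another build than the values.

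Within a gene, low RPKM values are whole multiples of the value of 1 read. From these steps the number of reads behind each library's values was recovered as 23253216, 23263095 and 19398694 for AKIT replicates 1 to 3 and 17657634 and 16242864 for E8 replicates 1 and 2. With a tolerance of 0.02 reads, 100% of the 19892 genes above 0 gave whole reads in every library, and the reads over genes summed to 99.0% of each total. A gene of 1 kb with 1 read has 0.043 to 0.062 RPKM, and a value of 0 allows up to 3 reads (counting error only). Recovered reads were used for depth, the comparison of library pairs, the simulation, 1 alternative fit and the tests on single AKIT libraries. The chi-square per gene between E8 replicates 1 and 2 was 3.7, above the 1 that sampling of reads alone gives, and 19.8 to 38.3 between AKIT libraries, so that each library counted as 1 replicate.

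The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(RPKM + 1), for genes with a mean of at least 0.5 RPKM over the 5 libraries, two-sided, with Benjamini-Hochberg adjustment over 14776 genes at 0.05. No covariate and no replicate block were used. Standard errors are those of the moderated test. Gene lists were tested with camera (preset inter-gene correlation 0.01, adjusted over the 38 lists with at least 5 tested members) and also with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. Each symbol had 1 row in the table. Counts "adjusted over the list alone" come from the same p-values adjusted within a list. The 39 lists cover core, naive and primed pluripotency, HERVH-linked transcripts, targets of Wnt, FGF and ERK, TGF-beta and Nodal, and BMP, calcineurin and NFAT, and GSK3 and DYRK kinases. They also cover markers of primitive streak and mesoderm, endoderm, neuroectoderm, neural crest, trophoblast and amnion, and fibroblasts. The remaining lists hold cholesterol and fatty acid synthesis, glycolysis, hypoxia, the respiratory chain, ATF4, the unfolded protein response, heat shock, p53, NRF2, aryl hydrocarbon receptor, metallothioneins, iron, insulin and FOXO, cell cycle, growth arrest, adhesion, interferon, apoptosis, imprinted genes, ribosomal proteins, histones and immediate early genes. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be added.

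By that rule POU5F1, SOX2 and NANOG were always named. The 6 largest changes in each direction were named among genes with adjusted p under 0.05, a mean of at least 5 RPKM in the higher group and no overlap between the groups. From each list up to 3 called members were named by size of change, or, where none passed, the 2 with the smallest p. The rule took 106 genes, of which 104 are named in the text. XIST and Y-linked genes were left out.

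The fit was tested on simulated reads for the comparison of AKIT with E8 (14676 genes, 200 of them changed). Of changes of 1.5-fold, 2-fold and 4-fold, 35.8%, 89.6% and 100% were recovered, with 0 of the wrong sign. There were 26 false calls among unchanged genes, 14.8% of all calls, above the nominal share. Of these, 25 lay in genes with fewer than 30 reads per library on average, and without such genes the share was 0.7%. In the real libraries 139 of the 2950 calls had so few reads. The simulation had a dispersion of 0.0109 and 200 changed genes. In the real libraries 20% of tested genes were called. The chi-square per gene was 3.7 between E8 libraries and 19.8 to 38.3 between AKIT libraries. The simulated shares therefore do not give the share of false calls in the real data. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 2 RPKM, median-of-ratios scaling, quantile normalization, limma without a trend, array weights, a replicate block, a minimum log2 change of 1, and each library left out in turn. Chosen after seeing the data were voom on the recovered reads and the removal of each library's loess trend (span 0.3) on gene length or on GC content. GC content and named pseudogenes came from GENCODE release 29 (GRCh38), to which 93.3% of the rows were matched by symbol. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.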

Results

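RNA sequencing was carried out on KhES-1, an established human embryonic stem cell line, grown on dishes coated with a laminin fragment at 0.5 µg per square cm. The cells were kept either in AKIT medium or in Essential 8 (E8), the control medium. E8 is a defined medium with added FGF2 and TGF-beta. AKIT is known as a medium in which inhibitors of GSK3, DYRK kinases and calcineurin stand in for those growth factors. The fragment on the dishes also carries the letters E8 in its name and was common to both media. The series has 3 libraries per medium. RPKM values (read counts scaled by gene length and library depth) of 3 AKIT libraries and of E8 replicates 1 and 2 were compared, and E8 replicate 3 was not analysed here. The values rested on 23253216, 23263095 and 19398694 reads in AKIT replicates 1, 2 and 3, and on 17657634 and 16242864 reads in E8 replicates 1 and 2. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Means are given ± SD with n = 3 for AKIT and n = 2 for E8. The log2 difference is AKIT minus E8 on the log2(RPKM + 1) scale, which understates changes of low genes, and is given ± its standard error. "Rose" and "fell" are used of genes past a Benjamini-Hochberg adjusted p of 0.05 in limma's moderated test over all genes.

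The comparison asked how the transcriptome of cells maintained in AKIT differed from that of cells in E8. EGR1, DUSP6 and 6 of 12 BMP targets, among them ID1 to ID4, fell in AKIT. NODAL, GDF3, KLF4, 9 metallothionein genes, 14 of 24 genes of cholesterol synthesis and 14 of 26 of the respiratory chain rose. The 4 lists named here passed camera with a preset correlation and not with an estimated one. With the latter, camera adjusted p was 0.372 for BMP targets, 0.832 for metallothioneins and the respiratory chain, and 0.834 for cholesterol synthesis. By fry, BMP targets, metallothioneins and the respiratory chain passed (fry adjusted p = 0.00315, 0.0419 and 0.0455), and cholesterol synthesis did not (0.0831). Of 14776 genes tested, 1214 rose and 1736 fell. Of these, 198 rose and 372 fell by at least 1 on the log2 scale. All 2950 called genes had AKIT libraries on one side of both E8 libraries, as did 54.4% of all tested genes, where chance gives 20%. The median log2 difference of all tested genes was -0.01.

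The first principal component (66.5% of the variance) separated the media, and the second (17.2%) separated AKIT replicate 2 from the other libraries. AKIT replicate 2 also lay nearer to E8 on the first component, at -15.2 against -26.4 and -26.2 for AKIT replicates 1 and 3 and 33.8 and 34.0 for E8. Without AKIT replicate 2, 2132 genes rose and 2619 fell, and 1194 of the 1214 and 1723 of the 1736 genes were called again. Without AKIT replicate 1, 791 rose and 1257 fell, and without AKIT replicate 3, 684 rose and 1117 fell. With a single E8 library the counts were 143 and 254 without E8 replicate 1, and 142 and 250 without E8 replicate 2. Those fits also ended the call of 52 of the 106 genes taken by the naming rule each.

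**Figure D1:**
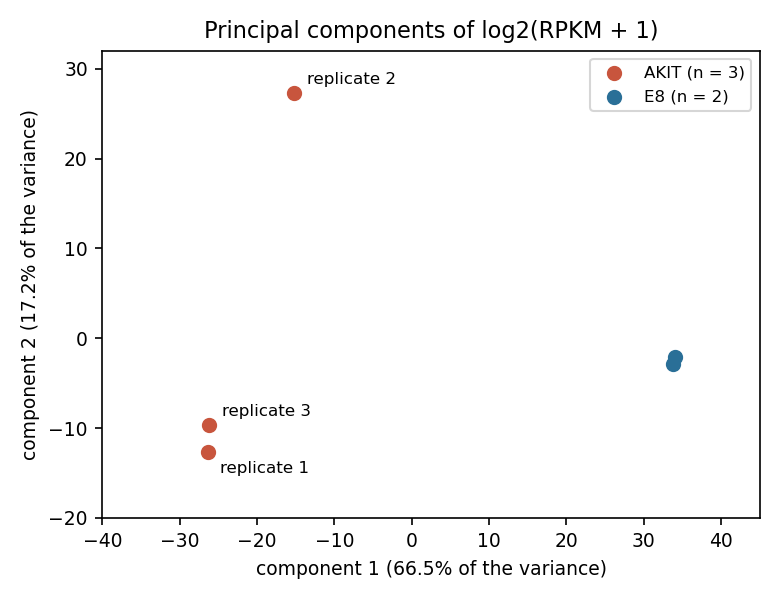
Principal components of log2(RPKM + 1) over 14776 genes, 1 point per library, with the first component (66.5% of the variance) on the x axis and the second (17.2%) on the y axis. The 2 E8 libraries lie together, AKIT replicates 1 and 3 lie together, and AKIT replicate 2 stands apart on the second component at 27.3.

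On the log2(RPKM + 1) scale the largest rise among genes open to the naming rule was that of LCP1, an actin-bundling protein, from 4.89 ± 0.185 RPKM in E8 to 102 ± 47.2 in AKIT (log2 difference 3.99 ± 0.41, limma adjusted p = 0.00196). LRFN5, a synaptic adhesion molecule, DACT1, a Dishevelled-binding antagonist of Wnt signalling, and the zinc finger gene ZNF600 rose by 2.93 ± 0.16, 2.90 ± 0.17 and 2.64 ± 0.17. Reads of ZNF600 may be split among related zinc finger genes, which leaves its level uncertain. NODAL, a TGF-beta family ligand of the pluripotent state, rose from 15.9 ± 0.0828 to 97.1 ± 12.6 RPKM (limma adjusted p = 0.000415). RPL10L, an intronless copy of RPL10, had 584 reads over the AKIT libraries (11.01 ± 5.49 RPKM) and 0 in both E8 libraries. Against a floor of 3 reads over both E8 libraries it was at least 101-fold higher, with the uncertainty of a near-identical copy.

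The largest falls on the same scale and under the same rule were those of NPTX1, a neuronal pentraxin, from 101.0 ± 5.19 to 3.10 ± 3.05 RPKM (log2 difference -4.94 ± 0.58, limma adjusted p = 0.0031), and of EGR1, an immediate early transcription factor, from 60.9 ± 1.08 to 2.69 ± 2.52 (-4.27 ± 0.45). PRICKLE1, a planar cell polarity gene, fell from 61.9 ± 1.52 to 4.28 ± 4.25 RPKM. DUSP6, a phosphatase of ERK, fell from 67.3 ± 3.86 to 4.97 ± 2.18, and SFRP1, a secreted Wnt antagonist, from 186 ± 0.135 to 21.0 ± 9.15. ID4, an inhibitor of helix-loop-helix factors, fell from 33.8 ± 0.162 to 3.09 ± 0.171. In AKIT, the libraries spread widely for NPTX1, EGR1 and PRICKLE1, with replicate 2 the highest at 6.43, 5.59 and 9.17 RPKM.

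**Figure D2:**
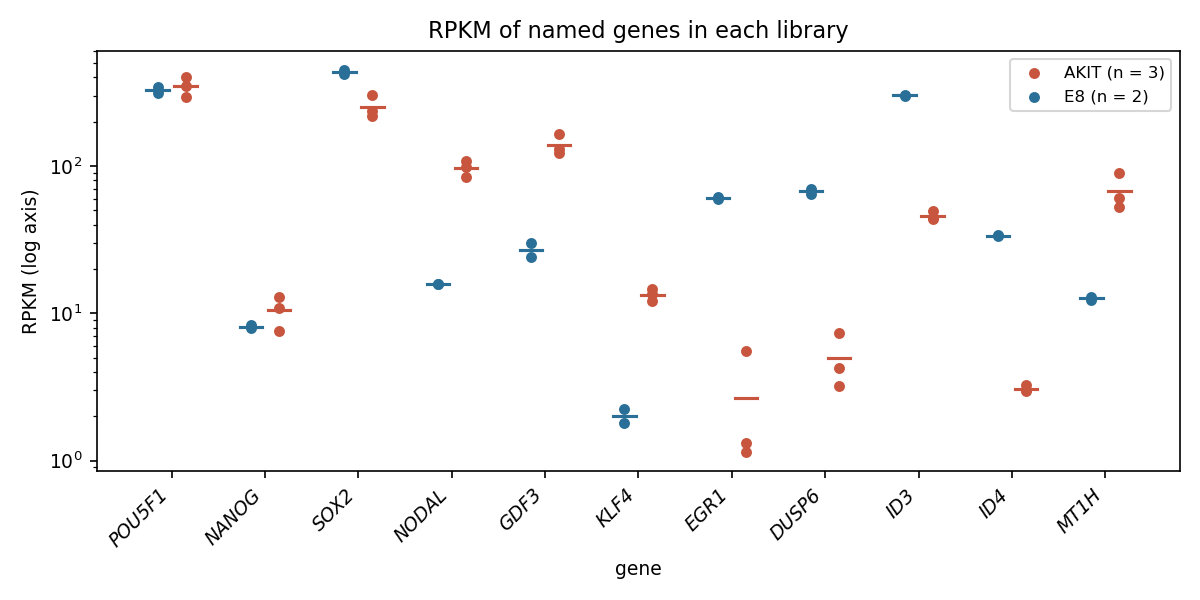
RPKM on a log axis of 11 named genes, with 1 point per library and a bar at the mean (E8 in blue, n = 2; AKIT in red, n = 3). POU5F1 and NANOG overlap between the media, SOX2, EGR1, DUSP6, ID3 and ID4 lie lower in AKIT, and NODAL, GDF3, KLF4 and MT1H lie higher.

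Of the pluripotency factors POU5F1, NANOG and SOX2, SOX2 passed the test. POU5F1 stood at 349 ± 52.0 RPKM in AKIT and 328 ± 21.0 in E8 (log2 difference 0.08 ± 0.15, limma adjusted p = 0.727), with a 95% interval of the difference from -0.26 to 0.43. NANOG stood at 10.5 ± 2.69 and 8.15 ± 0.235 RPKM (0.30 ± 0.20, limma adjusted p = 0.322). Without AKIT replicate 2 the difference of NANOG was 0.49 and passed (limma adjusted p = 0.0198, with 0.0198 to 0.626 over all alternatives). SOX2 fell from 435 ± 21.8 to 254 ± 45.3 RPKM (-0.79 ± 0.16, limma adjusted p = 0.0162), a call that ended without AKIT replicate 3 (limma adjusted p = 0.0525) and without E8 replicate 1 (0.152) or 2 (0.118), within a range of 0.00113 to 0.152 over all alternatives. Of the 21 tested members of the list, 3 rose and 3 fell, or 3 and 4 adjusted over the list alone. The largest of these changes were the rise of GDF3, a TGF-beta family ligand (27.1 ± 4.16 to 140 ± 22.4 RPKM), the fall of FOXD3, a forkhead factor (99.4 ± 8.03 to 21.2 ± 8.08), and the rise of DPPA3 from 0.362 ± 0.260 to 3.93 ± 1.07. As a set the list did not pass (camera adjusted p = 0.566). Of its members, 5 rose and 5 fell without AKIT replicate 2, and 1 fell with either E8 library left out.

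Of 13 tested naive markers, 5 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.79e-05; camera adjusted p = 0.372 with an estimated correlation). KLF4 rose from 2.02 ± 0.307 to 13.4 ± 1.31 RPKM and FGF4 from 2.91 ± 0.409 to 15.2 ± 1.12. The other naive genes called were DPPA3, TBX3 and NLRP7, the last 2 named after their values were seen. KLF17, a factor of the naive state, did not reach the filter, at a mean of 0.0183 RPKM in AKIT and 0 in E8. Of 15 primed markers, 7 fell and 2 rose, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00436; camera adjusted p = 0.832 with an estimated correlation). OTX2, a homeobox gene, fell from 145 ± 6.49 to 34.3 ± 22.1 RPKM, with AKIT replicate 2 at 59.7. Its adjusted p was 0.0136 in limma, 0.0502 without AKIT replicate 3, and 8.69e-05 to 0.101 over all alternatives. DLK1, a Notch-family ligand gene that is imprinted, rose from 2.62 ± 0.0758 to 17.7 ± 3.07. With E8 replicate 1 or 2 left out, 4 and 3 primed markers fell and 1 and 2 rose. Of the 3 tested transcripts linked to HERVH elements, HHLA1 (log2 difference 2.23 ± 0.12) and ABHD12B (0.83 ± 0.15) rose. Adjusted over the list alone, 2 rose and 1 fell, and the list was too short for a set test. In this list 1 also fell without AKIT replicate 2, and 1 rose with either E8 library left out.

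Of 12 tested BMP targets, 6 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 6.86e-06; camera adjusted p = 0.372 with an estimated correlation). ID3 fell from 302 ± 0.962 to 45.8 ± 3.49 RPKM and ID2 from 85.6 ± 3.74 to 15.5 ± 3.82, beside ID4 above. ID1 and SMAD7, an inhibitory SMAD, also fell, as did BAMBI, a pseudoreceptor that is also on the Wnt list (42.8 ± 3.66 to 11.97 ± 0.192 RPKM). Of 16 TGF-beta and Nodal targets, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.449). NODAL and GDF3 led the rises, with SKIL, a repressor of SMAD signalling, at a log2 difference of 1.10 ± 0.09. Of this list, 3 rose and 0 fell with either E8 library left out.

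Among 22 FGF and ERK targets, 6 fell and 2 rose, or 9 and 4 adjusted over the list alone, and the set did not pass (camera adjusted p = 0.208). Without AKIT replicate 2, 9 fell and 3 rose, and the set passed (camera adjusted p = 0.0492, with 0.0492 to 0.401 over the alternatives with the preset correlation). With an estimated correlation, all libraries used, its camera adjusted p was 0.834. On 1 E8 library, whichever was left out, 3 fell and 0 rose. EGR1 and DUSP6 had the largest falls, followed by FOS, an immediate early gene (22.8 ± 0.922 to 10.4 ± 4.31 RPKM, limma adjusted p = 0.0473). The 2 that rose, named after their values were seen, were ETV4 and IL17RD (log2 differences 0.48 and 0.51). Of 15 immediate early genes, 7 fell and 1 rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00183; camera adjusted p = 0.834 with an estimated correlation). IER2 fell from 257 ± 10.4 to 114 ± 16.8 RPKM and EGR3 from 2.44 ± 0.552 to 0.356 ± 0.370, with AKIT replicate 2 the highest at 0.783 against 0.172 and 0.115. Without AKIT replicate 3, 4 of these genes fell, and 2 and 3 without E8 replicates 1 and 2.

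Of 19 Wnt and beta-catenin targets, 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.852). The median of this list was 0.04, its mean -0.09 (log2), and camera's direction up. SP5, a transcription factor induced by beta-catenin, rose from 0.465 ± 0.370 to 7.97 ± 4.02 RPKM, while PRICKLE1 and BAMBI fell. PRICKLE1, the planar cell polarity gene above, had the largest change of the list (log2 difference -3.87). Also called, and named after their values were seen, were TCF7, which rose (1.10), and NOTUM, which fell (-0.67). In this list 3 rose and 5 fell without AKIT replicate 2, and 1 rose and 1 fell with either E8 library left out. Of 13 genes of calcineurin and NFAT, 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.161). RCAN2, a regulator of calcineurin, fell from 4.997 ± 0.389 to 1.38 ± 0.237 RPKM, and PPP3CA, a catalytic subunit of calcineurin, from 13.7 ± 1.13 to 7.69 ± 0.395. With either E8 library left out, 1 gene of this list fell and 0 rose, and 0 rose without AKIT replicate 3. Of 12 genes for GSK3, DYRK and related kinases, 2 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.566). These were DYRK1B (-0.58 ± 0.14) and DYRK3 (-0.48 ± 0.13), whose calls ended when any 1 of AKIT replicates 1 and 3 and the E8 libraries was left out.

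**Figure D3:**
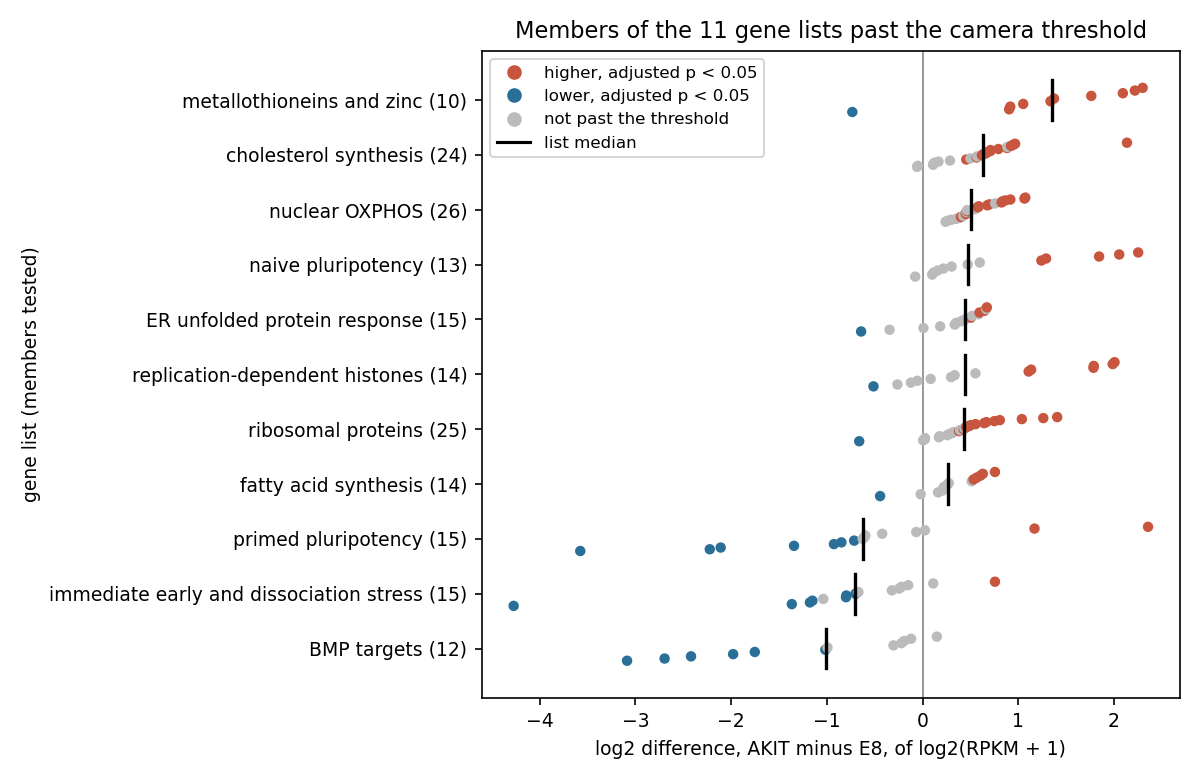
Log2 difference between AKIT and E8 of each tested member of the 11 gene lists past the camera threshold, with lists on the y axis, red and blue points for genes that rose or fell, grey points for the rest and a black bar at the list median. None of the 11 lists passes with an estimated correlation, and the list medians run from -1.005 for BMP targets to 1.35 for metallothioneins.

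No list of markers of differentiated lineages passed as a set, and called markers went both ways. Of 8 tested primitive streak and mesoderm markers, 2 rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.208). These were FGF8 (0.838 ± 0.402 to 6.32 ± 1.12 RPKM) and KDR, a VEGF receptor (log2 difference 1.82 ± 0.18). The set passed without AKIT replicate 3 (camera adjusted p = 0.0116), within a range of 0.0116 to 0.388 over the alternatives with the preset correlation. With an estimated correlation, all libraries used, its camera adjusted p was 0.834. Of 7 endoderm markers, FOXA2 rose (1.28 ± 0.20) and HHEX fell (-1.04 ± 0.20), with the same counts, 1 and 1, adjusted over the list alone (camera adjusted p = 0.567). Both calls ended without either E8 library. Of 10 neuroectoderm markers, 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.653). TUBB3, a neuronal tubulin, rose from 132 ± 5.94 to 203 ± 22.3 RPKM beside DLK1, and SOX3, a SOXB1 factor, fell from 29.3 ± 3.18 to 5.85 ± 0.391. Of 8 neural crest markers, 3 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.25). NGFR, a neurotrophin receptor, fell by 1.93 on the log2 scale, TFAP2A by 1.32 and SOX9 by 0.86, and 1 marker of this list fell with either E8 library left out. TFAP2A was highest in AKIT replicate 1, at 0.738 RPKM against 0.233 and 0.206. In the neuroectoderm list 3 fell without AKIT replicate 2, and 1 rose with either E8 library left out. In the neural crest list 1 rose without AKIT replicate 2.

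Of 9 trophoblast and amnion markers, 4 fell and 0 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.208). IGFBP3 fell from 25.2 ± 1.46 to 8.82 ± 4.30 RPKM and KRT7 from 5.23 ± 0.0834 to 1.59 ± 0.447. The set passed without AKIT replicate 1 (camera adjusted p = 0.0129, with 0.0129 to 0.482 over the alternatives with the preset correlation). With an estimated correlation, all libraries used, its camera adjusted p was 0.834. Of 12 fibroblast and mesenchyme markers, 4 fell and 0 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.567). S100A4 fell from 21.8 ± 2.48 to 6.80 ± 1.18 RPKM, THY1 by 0.71 and COL6A3 by 0.65 on the log2 scale. The median of this list was -0.15, its mean 0.03 (log2), and camera's direction down. Without AKIT replicate 3, 4 members of this list rose and 1 fell, and 2 fell without AKIT replicate 1. In each of these lists 1 rose without AKIT replicate 2, as did 1 trophoblast and amnion marker without AKIT replicate 3. With either E8 library left out, 1 marker of each of these lists fell. Some markers of the lineage lists, chosen after their values were seen, differed widely among the AKIT libraries. COL3A1 was at 5.63, 2.15 and 0.141 RPKM in AKIT replicates 1, 2 and 3 and at most 0.041 in E8. LUM was at 5.81, 1.83 and 0.024 in AKIT and 0 in E8, and TFAP2B at 2.40, 0.060 and 0.018 in AKIT and 0 in E8.

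**Figure D4:**
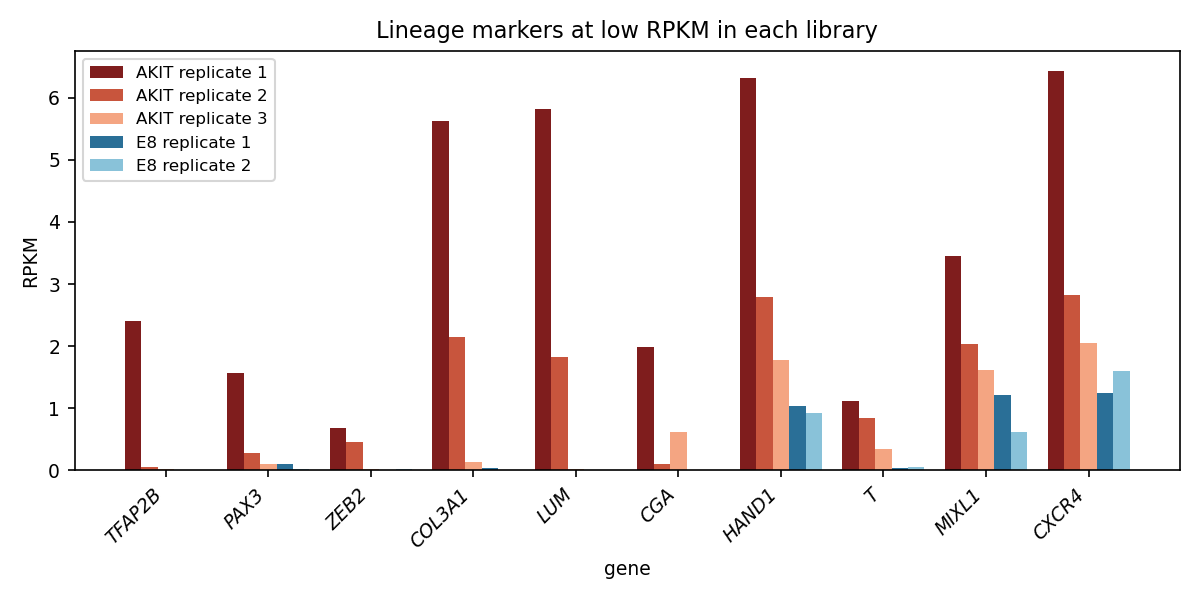
RPKM of 10 markers of mesoderm, endoderm, neural crest, trophoblast and mesenchyme in each library, as bars from 0, chosen after their values were seen. AKIT replicate 1 holds the highest bar of each of these genes, for example 5.81 RPKM of LUM against 1.83 and 0.024 in AKIT replicates 2 and 3. Of mesenchyme markers not drawn, COL1A1 was lowest there of all libraries at 32.5 RPKM. COL1A2 and POSTN were highest there of all libraries, at 15.6 and 0.56, and TAGLN of the AKIT libraries, at 103.

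Of 24 tested genes of sterol synthesis, 14 rose and 0 fell, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.99e-07; camera adjusted p = 0.834 with an estimated correlation). INSIG1, a regulator of SREBP processing, rose from 23.3 ± 4.49 to 46.5 ± 12.7 RPKM. Of 14 genes of fatty acid synthesis, 5 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00333; camera adjusted p = 0.832 with an estimated correlation). PNPLA3 rose by 0.76 ± 0.11, SCD, the stearoyl-CoA desaturase, by 0.63 ± 0.15 and ACSS2 by 0.60 ± 0.17 on the log2 scale. With E8 replicate 1 or 2 left out, 1 sterol gene and 0 fatty acid genes rose, and 0 fatty acid genes fell without any 1 of AKIT replicates 1 and 3 and the E8 libraries.

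Nuclear genes of the respiratory chain were all higher in the means, and 14 of 26 rose with 0 falling, or 22 and 0 adjusted over the list alone (camera adjusted p = 5.55e-10; camera adjusted p = 0.832 with an estimated correlation). COX5A rose by 1.07 ± 0.11 on the log2 scale, COX6C from 5.09 ± 1.03 to 11.7 ± 0.589 RPKM and UQCRH from 87.3 ± 1.03 to 169 ± 39.8. Of 25 cytoplasmic ribosomal protein genes, 13 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 9.95e-07; camera adjusted p = 0.832 with an estimated correlation). RPL23, RPL18 and RPL11 rose by 1.41 ± 0.12, 1.26 ± 0.12 and 1.04 ± 0.14 on the log2 scale. Processed pseudogenes share sequence with many of these genes, which leaves their levels uncertain. AKIT replicate 2 stood nearest to E8, with a median log2 difference of the respiratory chain list of 0.34 against 0.73 and 0.61 in AKIT replicates 1 and 3. The respiratory chain and ribosomal counts of rises were 22 and 18 without AKIT replicate 2, 7 and 7 without AKIT replicate 1, and 6 and 6 without AKIT replicate 3. They were 3 and 2 without E8 replicate 1, and 2 and 3 without E8 replicate 2, and the 1 ribosomal fall ended in all of these but the fit without AKIT replicate 2.

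Metallothioneins bind zinc and copper. Of the 10 genes of the zinc list, 9 rose, all metallothioneins, and 1 fell, the zinc exporter SLC30A1, with the same counts adjusted over the list alone (camera adjusted p = 6.16e-06; camera adjusted p = 0.832 with an estimated correlation). MT1H rose from 12.6 ± 0.326 to 67.9 ± 19.5 RPKM, MT1E from 12.4 ± 0.731 to 57.4 ± 16.5 and MT1M from 1.09 ± 0.633 to 8.69 ± 2.28. The MT1 genes are near-identical copies, so reads may be split between them. Without E8 replicate 1, 4 of them rose. Of 14 replication-dependent histone genes, 6 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00178; camera adjusted p = 0.834 with an estimated correlation). HIST1H1C rose from 17.8 ± 1.05 to 73.8 ± 11.1 RPKM, HIST1H2AC from 10.7 ± 2.42 to 39.2 ± 4.05 and HIST1H2BJ from 1.67 ± 0.532 to 9.77 ± 2.13, with the same uncertainty of related copies. The 1 fall of the zinc list and that of the histone list ended without any 1 of AKIT replicates 1 and 3 and the E8 libraries, and 4 histone genes rose without E8 replicate 1.

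Of 15 genes of the endoplasmic reticulum stress response, 4 rose and 1 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.00333; camera adjusted p = 0.834 with an estimated correlation). The chaperone gene CANX rose by 0.65 ± 0.11 and CRELD2 by 0.67 ± 0.15, and DNAJB9 fell by 0.64 on the log2 scale. In this list 12 rose without AKIT replicate 2, and with either E8 library left out 0 rose. Its 1 fall ended in those fits on 1 E8 library and without AKIT replicate 1. Of 22 ATF4 and amino acid response genes, 6 fell and 0 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.382). ASNS, asparagine synthetase, fell from 40.2 ± 1.476 to 17.6 ± 3.75 RPKM, SLC7A3, an arginine transporter, from 81.4 ± 1.31 to 38.7 ± 3.76, and CHAC1 from 49.4 ± 5.72 to 28.1 ± 3.53. Of 12 heat shock genes, HSPD1 rose (0.45 ± 0.10) and HSPA1A fell (-0.76 ± 0.20), the same counts, 1 and 1, adjusted over the list alone (camera adjusted p = 0.882). HSPA1A has a near-identical copy, HSPA1B. Without AKIT replicate 2, 3 genes of the ATF4 list and 5 of the heat shock list rose, and with either E8 library left out 1 ATF4 gene fell and 0 heat shock genes were called. In the heat shock list 0 rose and 2 fell without AKIT replicate 1, and 0 were called without AKIT replicate 3.

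Of 17 p53 targets, BAX rose (0.51 ± 0.11) and BBC3 fell (-0.44 ± 0.10), the same counts, 1 and 1, adjusted over the list alone (camera adjusted p = 0.376). Of 18 apoptosis regulators, 3 rose and 4 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.567). BMF and PMAIP1, proapoptotic BH3-only genes, fell by 1.14 and 0.95 on the log2 scale and XIAP, a caspase inhibitor, rose by 0.59 ± 0.10. Of 12 NRF2 targets, TALDO1 rose (0.84 ± 0.09) and SRXN1 fell (-0.76 ± 0.10), the same counts, 1 and 1, adjusted over the list alone (camera adjusted p = 0.248). Of 6 aryl hydrocarbon receptor targets, 2 fell and 0 rose, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.796). These were TIPARP (9.46 ± 0.789 to 3.65 ± 1.30 RPKM) and AHRR, the receptor's repressor (-0.57 ± 0.14). The median of this list was 0.05, its mean -0.09 (log2), and camera's direction down. Without AKIT replicate 2, 4 p53 targets, 3 NRF2 targets and 2 aryl hydrocarbon receptor targets rose. With either E8 library left out, 2 apoptosis regulators fell and 0 rose, and 0 p53 or aryl hydrocarbon receptor targets were called. NRF2 targets then had 0 falls, with 1 rise without E8 replicate 1 and 0 without E8 replicate 2. With AKIT replicate 1 or 3 left out, 2 apoptosis regulators, 0 p53 targets and 1 aryl hydrocarbon receptor target fell.

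No glycolysis gene of 19 passed limma's test, also adjusted over the list alone (camera adjusted p = 0.567). The smallest p-values were those of PFKM (-0.38 ± 0.12, limma adjusted p = 0.0586) and GPI (0.41 ± 0.15, limma adjusted p = 0.0926), which both passed without AKIT replicate 2 (limma adjusted p = 0.0325 and 0.0404, with 0.024 to 0.383 and 0.0359 to 0.39 over all alternatives). The glycolysis set passed without AKIT replicate 3 (camera adjusted p = 0.0253, with 0.0253 to 0.967 over the alternatives, among them 0.885 with an estimated correlation). Of 16 hypoxia response genes, 2 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.406). STC1 fell from 82.8 ± 3.93 to 11.2 ± 6.04 RPKM and ADM from 199.9 ± 5.42 to 38.6 ± 18.4. Of 9 iron genes, HEPH, a ferroxidase, fell (18.5 ± 0.332 to 6.54 ± 1.05 RPKM) and 0 rose, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.567). Of 16 insulin and FOXO genes, 3 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.571). FOXO4 rose from 35.5 ± 1.05 to 84.5 ± 8.20 RPKM, FOXO1 fell from 50.6 ± 2.49 to 24.5 ± 1.86 and CITED2 from 101.8 ± 1.78 to 44.1 ± 9.29. In the hypoxia list 4 genes fell without AKIT replicate 2 and 2 rose without AKIT replicate 3, and with either E8 library left out 0 hypoxia genes and 1 FOXO list gene fell. In the glycolysis list 1 rose and 1 fell without AKIT replicate 2, and 2 rose without AKIT replicate 3. In the iron list 2 rose without AKIT replicate 2 and 1 without AKIT replicate 1, as did 2 of the FOXO list without AKIT replicate 1.

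Cell cycle genes were mostly not called. Of 26, 1 rose and 4 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.883). CCNE2, a cyclin of the G1/S transition, fell from 3.99 ± 0.0821 to 1.33 ± 0.1603 RPKM and PLK1, a mitotic kinase, by 0.51 on the log2 scale, while MCM6, a subunit of the replicative helicase, rose by 0.54 ± 0.12. Of 9 growth arrest genes, 4 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.449). GAS1 fell from 6.73 ± 0.206 to 2.11 ± 0.817 RPKM, CDKN1C by 0.86 and GADD45B by 0.75 on the log2 scale. Of 20 adhesion and laminin receptor genes, 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.406). CLDN3 fell from 47.8 ± 5.43 to 18.7 ± 0.736 RPKM and ITGA3, an integrin subunit that binds laminin, from 9.61 ± 0.0469 to 4.06 ± 0.142. LAMB1, a laminin chain, rose from 7.68 ± 0.553 to 17.7 ± 3.07. In the cell cycle list 4 genes rose and 6 fell without AKIT replicate 2, and 2 fell without AKIT replicate 1 or 3. In the adhesion list 2 rose and 6 fell without AKIT replicate 2, and 2 growth arrest genes fell without AKIT replicate 3. With either E8 library left out, 1 cell cycle gene, 0 growth arrest genes and 2 adhesion genes fell, and 0 genes of these lists rose.

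Of 11 interferon response genes, 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.779). IFITM1 rose from 794 ± 52.4 to 1621 ± 356 RPKM and IFITM3 from 473 ± 22.5 to 794 ± 120, genes similar enough to share reads, and IFI6 fell by 0.79 on the log2 scale. Of 15 imprinted genes, 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.567). The largest of these changes was that of DLK1, followed by NLRP2 (0.86 ± 0.14) and CDKN1C. The median of this list was -0.01, its mean 0.20 (log2), and camera's direction up. In the imprinted list 4 fell without AKIT replicate 2 and 1 without AKIT replicate 1 or 3. The fall in the interferon list ended without AKIT replicate 3. With either E8 library left out, 0 interferon genes were called, and 1 imprinted gene rose and 0 fell. No list passed camera with an estimated inter-gene correlation in place of the preset one of 0.01, and 10 passed fry. For BMP targets and naive markers the correlation was estimated at only 0.017 and -0.056. Their unadjusted camera p still rose from 9.03e-07 and 1.55e-05 to 0.0177 and 0.0196. For cholesterol synthesis, the respiratory chain and metallothioneins the correlation was estimated at 0.635, 0.482 and 0.417. It was 0.713 for the endoplasmic reticulum stress response, 0.539 for immediate early genes, 0.534 for histones and 0.373 for ribosomal proteins. Primed markers and fatty acid synthesis had 0.142 and 0.046. Where the estimate lies far above 0.01, camera p-values with the preset correlation are likely to overstate the evidence. With an estimated correlation camera works on the 3 residual degrees of freedom, which leaves little power over 38 lists. A failure there does not show that a list's genes are unchanged. The lists past camera that did not pass fry were cholesterol synthesis (fry adjusted p = 0.0831), the endoplasmic reticulum stress response (0.17), ribosomal proteins (0.0526), histones (0.0831) and immediate early genes (0.132).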

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

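The values with voom on recovered reads and with a length or GC trend removed were chosen after the data were seen, and the other alternatives before. The numbers of genes that rose and fell, 1214 and 1736, stayed within 1.5 times under both pseudocounts, both filters, both scalings, limma without a trend, voom (1236 and 1905) and the length (1596 and 1785) and GC (1284 and 1420) corrections. They were 2269 and 2740 with array weights, which weight the E8 libraries most and AKIT replicate 2 least, and 198 and 372 with a minimum log2 change of 1. With each library left out in turn, 142 to 2132 genes rose, 250 to 2619 fell and 11 to 13 lists passed. The lowest counts left 1 E8 library, assumed to vary like the AKIT libraries, and the highest left out AKIT replicate 2. With the replicate block 492 rose and 824 fell, and 2 more lists passed camera, primitive streak and mesoderm (adjusted p = 0.0233) and glycolysis (0.0263). AKIT and E8 share only the replicate numbers 1 and 2, whose paired deviations correlated at -0.001 and 0.025, so the numbers were not taken to pair the samples. Of the 11 lists past the threshold, 0 passed with an estimated correlation. By fry 10 lists passed (5 of the 11 ended, and 4 other lists entered: core pluripotency, TGF-beta and Nodal, calcineurin, apoptosis). Camera with an estimated correlation works on 3 residual degrees of freedom, which lowers its power, and no other cause was tested. No called gene changed sign in any of the fits, and no named gene or list reversed. Named genes whose call ended numbered 24 with the block, 14 without a filter, 6 with the GC correction and at most 3 under the scalings. The alternative without E8 replicate 3 was not run, because its values were not used here. Calls in genes with fewer than 30 reads per library are the least certain, since most false calls of the simulation lay there.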

Other observations

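All tests in this part were chosen after the results were seen. Gene families were scanned by symbol stem, 237 families of at least 8 tested genes, for more calls than other genes have (one-sided Fisher's exact test, Benjamini-Hochberg adjusted over families and directions). All 12 tested PCDHGA genes, gamma protocadherins, fell (median log2 difference -0.54). They share their last exons, so the 12 calls are not independent and no p is given for them. Of 45 genes with HIST symbols, 14 rose and 1 fell (Fisher adjusted p = 0.00103), and of 487 genes with ZNF symbols, zinc finger factors, 63 rose and 27 fell (Fisher adjusted p = 0.0159). Of 63 RPL and 45 RPS genes, 17 and 12 rose and 1 and 2 fell (Fisher adjusted p = 0.00103 and 0.0159). Fisher's test takes genes as independent, which members of a family need not be. The lists of ribosomal proteins and histones had estimated inter-gene correlations of 0.373 and 0.534. The Fisher p-values of these families therefore overstate the evidence. All 10 genes with MT symbols rose, among them the MT1 copies named above, so no p is given for them. The 13 SOX genes, of which 6 fell and 0 rose, did not pass (Fisher adjusted p = 0.102). Families with respiratory chain symbols did not pass either. Of these, 5 of 11 NDUFB, 4 of 14 NDUFA and 5 of 22 COX genes rose (Fisher adjusted p = 0.067, 0.552 and 0.679), and 0 of 8 NDUFS genes. The direction of each of these families was the same under median-of-ratios and quantile scaling.

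Some genes, chosen after their values were seen, were found in 1 medium almost alone. FGF17 was at 2.53, 3.66 and 1.52 RPKM in AKIT replicates 1, 2 and 3 and at 0.093 and 0 in E8. APLNR, the apelin receptor, was at 2.92, 1.40 and 0.319 against 0.058 and 0.095. Its reads were 263, 126 and 24 in AKIT replicates 1, 2 and 3 and 4 and 6 in E8. For APLNR a difference between media therefore cannot be told apart from a difference among the AKIT libraries. CTCFL, a paralog of CTCF, was at 0.967 and 1.16 RPKM in E8 and at most 0.060 in AKIT. EN1 and EN2, homeobox genes of the midbrain, stood out more sharply in AKIT replicate 1, at 1.66 and 2.52 RPKM. They were at 0.290 and 0.152 in AKIT replicate 2, 0 in AKIT replicate 3 and at most 0.036 in E8.

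Of 35 markers of the 6 lineage lists with a mean under 1 RPKM in E8 and at least 20 reads in AKIT, 22 were highest in AKIT replicate 1, 11 in replicate 2 and 2 in replicate 3. Matched random sets of other rare genes had a median of 12 highest in replicate 1 (permutation p = 0.0006 over 10000 sets, which overstates the evidence, since genes are not independent and the pattern was noticed in these markers). Reads of TFAP2B, 161, 4 and 1 in replicates 1, 2 and 3, and the 32.9% of other rare genes highest in replicate 1 speak against counting noise or a shift of all rare transcripts as the whole cause. RNA of 1 kind of other cell in replicates 1 and 2 would split all markers in 1 ratio if the AKIT cells themselves had none. The chi-square per degree of freedom of that split was 16.9 over 20 markers (median of random sets 6.11, random-set p = 0.023), with 185 and 124 reads of ZEB2. AKIT replicate 3 had few reads of these markers, with 1 each of LUM and TFAP2B. It had some of them all the same, with CGA at 0.611 RPKM (10 reads) against 0.102 (2 reads) in replicate 2, and T at 0.348 (17 reads). The test therefore cannot exclude 1 kind of other cell beside such expression. Several kinds of differentiating cells in changing shares also stay open, as a hypothesis. No biological explanation from the design was tested, since the labels put the 3 libraries in 1 group.

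AKIT replicate 2 stood apart from AKIT replicates 1 and 3, and removing each library's trend on gene length left 15.4% of the variance on the second component, from 17.2%, with replicate 2 still apart at 25.3, so a length trend was not the whole of it. Rows of small nucleolar RNAs and microRNAs, most of which lie in introns, had a median log2 ratio of 0.468 over the other AKIT libraries. Of 414 such rows, kept at a mean of at least 1 RPKM over the AKIT libraries, 44.2% were highest of all libraries in replicate 2. The shares were 9.7% and 13.5% in AKIT replicates 1 and 3, and 20% if all libraries were alike. That filter favours a maximum in AKIT, so 20% is only a rough reference, but it treats the AKIT libraries alike. A mixture with E8 RNA puts expected levels between its sources, but short rows kept from a mean of 1 RPKM can exceed them by sampling. The shares argue against such a mixture alone for these rows, and not against one beside another cause. Over 43 genes much lower in AKIT, replicate 2 lay a median of 6.0% of the way to E8 (robust SD 11 points against 7.3 from replicate spread, and 10th to 90th percentiles of -2.1 to 30.4 against -5.8 to 10), and over 27 genes much higher in AKIT, which were tried first, 22.5% (robust SD 26.0 against 34.2). Percentiles of the higher genes ran from -41.8 to 63.1, no wider than the -111.5 to 22.8 from replicate spread. Those of the lower genes were wider, but their robust SDs of 11 and 7.3 were not far apart. Whether all genes have 1 share therefore cannot be decided. Both sets were chosen on replicates 1 and 3, which biases the share toward E8. A small admixture thus cannot be told apart from replicate spread in the genes lower in AKIT. More unspliced RNA may account for the small RNA rows but was found from the same rows, and no biological explanation was tested.

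Respiratory chain and ribosomal protein genes had median log2 differences of 0.51 and 0.43, and with the gene length trend removed 0.497 and 0.389, and with the GC trend removed 0.53 and 0.458, and both lists still passed camera with the preset correlation, against these trends as the whole cause. Without a correction neither list passed camera with an estimated correlation (camera adjusted p = 0.832 for both), and ribosomal proteins did not pass fry (fry adjusted p = 0.0526). The 9 respiratory chain genes without a named pseudogene had a median of 0.465 (SD 0.165), and the 17 with one 0.557. Of the list's 14 called genes, 2 were among the 9. Pseudogenes were found by the gene's symbol followed by P, so those named otherwise were missed. The median of the 9 argues against reads shared with such named pseudogenes as the whole cause. A part in the 17, which hold most of the calls, stays open. For ribosomal proteins shared reads cannot be told apart from a change of the genes, since 0 of 25 lack a named pseudogene, and a response to the medium stays open for both lists as an untested hypothesis.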
